A study of Mus musculus with 1 sample.

How the data were processed

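Total RNA from ovarian surface epithelial cells of wild-type mice was extracted with a column kit, and biotin-labelled cRNA was made from 5 ug of it and measured on an Affymetrix expression array, per the labels' protocols. The deposited value table gives 1 intensity for each of 45101 probe sets. The submitters' processing notes name affy and RMA, a method that corrects background, normalizes between arrays and summarises the probes of a set. The versions, and which arrays were normalized together, are not given in the sources used here. RMA usually returns log2 values, whereas all 45101 deposited intensities were whole numbers on a linear scale up to 32341. The step that turned log2 values into whole linear numbers is not given in the sources used here. Rounding moves a value by up to 0.116 on the log2 scale at the lowest intensity of 6 and by 0.0154 at the background limit. RMA shrinks differences between low intensities, and normalization across arrays can move all values of this array in a way that 1 column cannot show.

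All intensities were put on the log2 scale. Probe sets were named through a table of the array's platform annotation. A total of 34945 probe sets had 1 gene symbol and gave 18193 genes. A further 932 probe sets had several symbols and 9160 had no symbol in that table, and both kinds were left out of gene counts, as were 64 control probe sets. Gene numbers of 34741 of the named probe sets matched the mouse reference gene table of assembly GRCm38.p6, and none of the symbols differed. The remaining 204 kept the symbol of the annotation. Genes without a named probe set were not analysed here. No genomic coordinates are given, since no genome build was named for the probe sets.

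The level of a gene was that of its brightest probe set. A gene was counted as above background when this level exceeded the 95th percentile of 126 probe sets for 112 genes of 4 families not expected in ovary. By construction about 5% of such probe sets, here 7, pass. The limit compares each probe set with a common background and takes no account of its affinity. There were 30 lists of genes for cell types, pathways and controls, with 375 members, of which 340 were measured. The number of members above background in each list was set against 10000 random lists of the same size from all named genes, matched on the number of probe sets per gene. A list was said to have more, or fewer, members above background where 2.5% of the random lists or less had as many, or as few. The place of list medians among those of random lists was also planned and computed, but is not reported, since probe sets of different genes differ in affinity. The percentages describe this library, and no p-value is given, since genes are not replicates. Members of these lists are well-studied genes, and random lists also hold little-studied genes, which could make the lists appear more often expressed. The genes named in the account of the lists were the first 3 measured members of every list in its written order, with Amhr2 added. Genes of the added families and the bright probe sets were named after the values were seen. The lists, the rule for names in them, the limit and the alternatives were fixed before the data were examined.

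The procedure was tested on simulated lists drawn from the 18193 genes. Of 200 lists of 10 random genes, 2 were called as having fewer members and none as having more. Of 200 lists of 15 random genes, 6 were called as fewer and 2 as more. All 50 lists of 10 genes that were all at background were called. Of 50 lists of 10 genes that were all above background 40 were called, and of 50 such lists of 15 genes all were. A short list that is fully expressed can therefore miss the call.

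The alternatives were a limit at the 90th or 99th percentile, a background from olfactory and vomeronasal receptors, from Y-linked genes or from genes restricted to other organs, the mean or the lowest probe set of a gene, the removal of probe sets with marked identifiers, which stand for several transcripts of 1 gene, for probes shared between genes or for possible cross-hybridisation, and random lists without matching. The spread between probe sets was also taken over genes above background only. An array has no read depth, and with 1 array the precision of every level is unknown. The computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.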

Results

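Gene expression was measured on a single Affymetrix mouse expression array hybridised with total RNA from ovarian surface epithelial cells of wild-type mice aged 3 months. The ovarian surface epithelium is the simple layer of mesothelial-type cells that covers the ovary. The series design names 3 mouse genotypes, and 1 wild-type sample was analysed here, so no comparison between genotypes was made and no value has a replicate error. The table held 45101 probe sets with intensities from 6 to 32341 and a median of 41. The spread between probe sets of the same gene was the only spread that 1 array offers, and it is not a replicate error.

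Of 18193 genes with a probe set paired with a single gene symbol, 11432 (62.8%) had at least 1 probe set above background. The background limit was an intensity of 46.5, or 5.54 on the log2 scale. It was the 95th percentile of 126 probe sets for olfactory, vomeronasal and bitter taste receptors and keratin-associated proteins, which have no expected role in ovary. The median of these background probe sets was 13. Among genes with 1 probe set 47.3% were above the limit, against 94.9% of genes with 6 or more probe sets. For 4204 of the 9010 genes with several probe sets, the probe sets lay on both sides of the limit. Within such genes the median SD between probe sets was 1.39 on the log2 scale, so levels of different genes were not ranked against each other, and list medians are given as a description only.

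**Figure D1:**
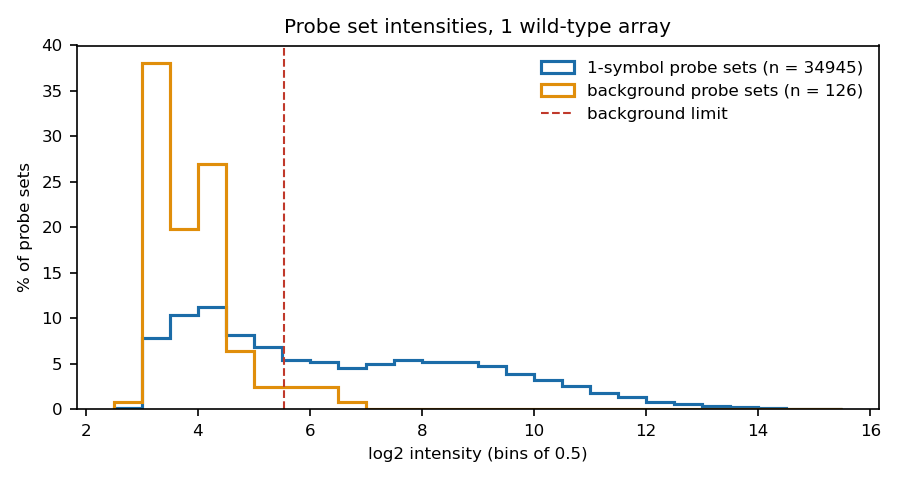
Distribution of log2 intensity (x axis, bins of 0.5) as the percent of probe sets (y axis) for 34945 probe sets with 1 gene symbol and for 126 background probe sets on the 1 wild-type array. The dashed line is the background limit of 5.54, which 55.1% of the probe sets with 1 symbol exceeded.

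The sample carried the transcripts of surface epithelium and mesothelium. All 15 markers of this list were above background, and 0.02% of 10000 random lists matched on the number of probe sets had as many. The median level of the list was 12.16 on the log2 scale. Krt8, a keratin of simple epithelia, had 3 probe sets between 3172 and 4573. Krt19, another simple-epithelial keratin, had an intensity of 4897. Upk3b, a uroplakin used as a mesothelial marker, had intensities of 14848 and 20836. The list kept its call under all 9 alternatives.

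Genes of epithelial adhesion and tight junctions were divided, with 8 of 12 measured members above background, which 53.1% of random lists matched or exceeded. Cldn3, a tight junction claudin, had 4 probe sets between 1276 and 3923. Epcam, an epithelial adhesion molecule, had intensities of 158 and 921. Cdh1, which encodes E-cadherin, the main adhesion protein of most epithelia, had 1 probe set at 95, above the limit of 46.5.

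Fibroblast and smooth muscle transcripts were also present. Of 10 fibroblast markers 9 were above background, and of 10 smooth muscle and pericyte markers 9 were. Neither count stood apart: 7.76% of random lists had as many as the fibroblast list and 11.1% as many as the smooth muscle list. The list medians of 10.32 and 10.77 on the log2 scale lay above 99.96% and 99.95% of those of random lists. The fibroblast count did stand apart with the limit at the 99th percentile of background and with the lowest probe set of each gene. Col1a1, a chain of fibrillar type I collagen, had intensities of 6440 and 8290. Dcn, the matrix proteoglycan decorin, had 1 probe set at 15048 and another at 47. Pdgfra, a growth factor receptor of fibroblasts, had 1 of 3 probe sets above the limit, at 916. Acta2, smooth muscle actin, had 23141 on its brightest probe set and 23 on its lowest. Tagln, an actin-binding protein of smooth muscle, had 22357, and Myh11, the smooth muscle myosin heavy chain, had 764 on 1 of its 2 probe sets and 21 on the other.

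Endothelial markers were mostly at background, with 3 of 10 above the limit. Pecam1 and Cdh5, junction proteins of endothelium, had intensities of 14 and at most 23. Kdr, a receptor for vascular endothelial growth factor, had 1813 and was 1 of the 3 members above the limit. As a count the list did not stand apart from random lists, of which 4.33% had as few.

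Markers of hormone-producing ovarian cells were divided. Of 9 measured granulosa cell markers 6 were above background, and of 7 measured theca and luteal markers 5 were. Random lists had as many or more in 54.8% and 62.6% of draws. Inha, the alpha subunit of inhibin, had 1438. Amh, anti-Müllerian hormone, had 58, close to the limit of 46.5, and Fshr, the follicle-stimulating hormone receptor, had 34, below it. Star, which moves cholesterol into mitochondria for steroid synthesis, had 3 probe sets between 947 and 1229. Cyp11a1, the first enzyme of steroid synthesis, had 1 of 3 probe sets above the limit, at 381, and Cyp17a1, an enzyme of androgen synthesis, had 18.

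Oocyte transcripts were not above background. None of the 10 oocyte markers passed the limit, and 0.08% of random lists had as few. Zp3, an egg coat protein, had 20, Gdf9, an oocyte growth factor, had 42, and Bmp15, another oocyte growth factor, had at most 18. With the limit at the 90th percentile of background, or with olfactory and vomeronasal receptors as the background, 3 of the 10 were above it and the list no longer stood apart.

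Of the blood and immune lists, the macrophage list had members above background in number. Of 11 macrophage markers 10 were above the limit, as many as in 0.91% of random lists. Csf1r, the receptor for macrophage colony-stimulating factor, had 3 probe sets between 80 and 527, C1qa, a complement component, had 244, and Adgre1, a macrophage surface receptor, had 47, at the limit of 46.5. This call ended under 3 of 9 alternatives: with the limit at the 90th percentile, with olfactory and vomeronasal receptors as the background, and with random lists not matched on probe sets.

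Neutrophil markers had 1 of 8 members above background, lymphocyte markers 3 of 9 and erythroid markers 0 of 4. S100a8 and S100a9, abundant calcium-binding proteins of neutrophils, had 13 and 12, and Csf3r, a neutrophil growth factor receptor, had 17. Cd3e and Cd3d, parts of the T cell receptor complex, had 46 and 39, and Cd79a, part of the B cell receptor, had 20. Alas2, the erythroid enzyme of haem synthesis, had 21, Slc4a1, the red cell anion exchanger, at most 31, and Hba-a1, an alpha-globin, 16. A probe set shared by the beta-globin genes had 148, and of 3 shared by Hba-a1 and Hba-a2 the highest had 85, both above the limit. The erythroid list had fewer members above background than random lists, of which 1.28% had as few, and kept that call under 3 of 9 alternatives. With the shared probe sets counted for Hba-a1, an alternative chosen after the values were seen, 1 of 4 members was above the limit, 4.91% of random lists had as few, and the call ended. With Hbb-b1 added in the same way, 2 of 5 were above it and 17.2% had as few. The lymphocyte list had no such call, but gained it under 5 of 9 alternatives, and the neutrophil list gained it under 3.

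Markers of neighbouring tissues were divided. Of 7 measured oviduct markers 3 were above the limit, and of 6 measured adipocyte markers 2 were. Neither count stood apart, since 30.3% and 14.6% of random lists had as few. Ovgp1, the oviduct glycoprotein, had 35, and Foxj1, a regulator of cilia, had 20. Pax8, a transcription factor of the oviduct epithelium, had 107 on 1 of 2 probe sets. Adipoq and Fabp4, adipocyte products, had 11 and at most 22, and Retn, an adipocyte hormone, had 58.

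**Figure D2:**
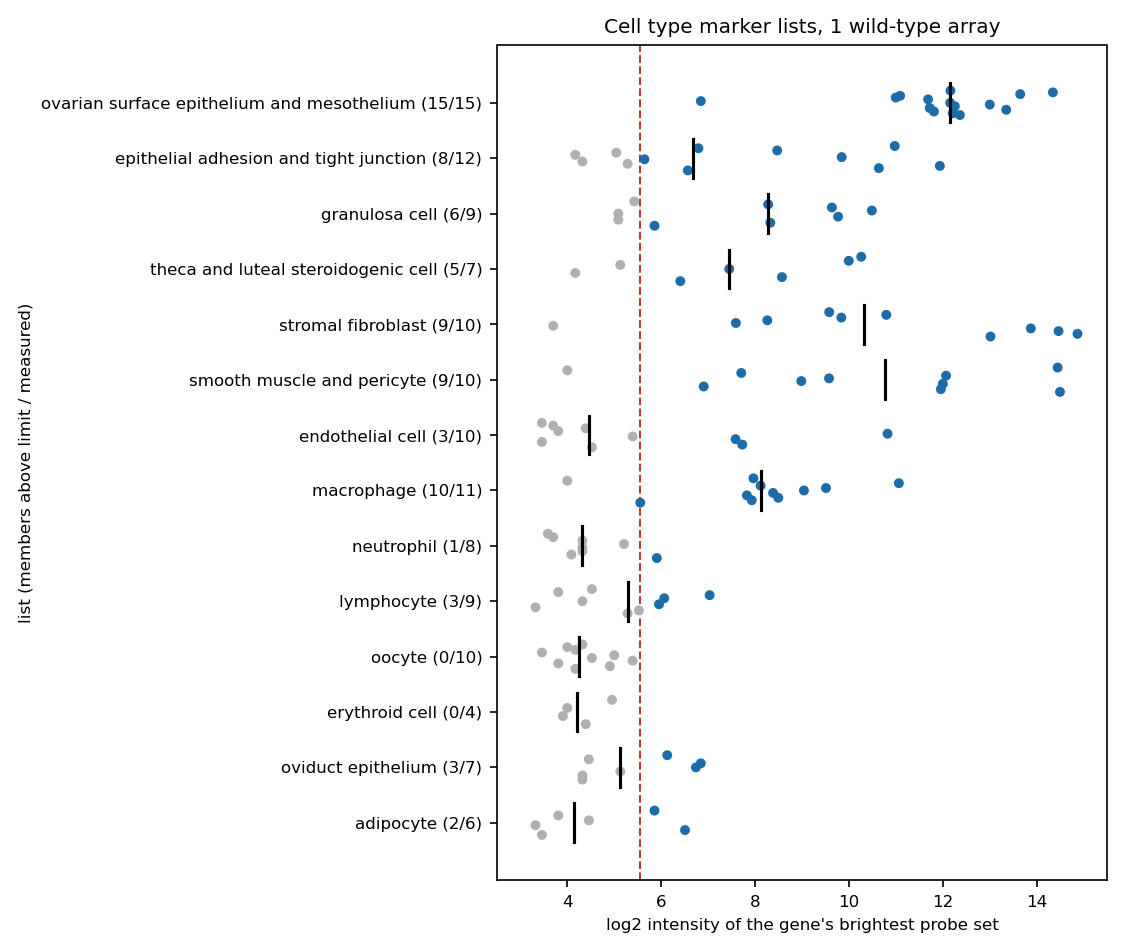
Log2 intensity of the brightest probe set (x axis) of each measured member of 14 cell type marker lists (y axis) on the 1 wild-type array. Each point is a gene, blue above and grey at or below the background limit of 5.54 (dashed line), and the black bar is the list median. All 15 surface epithelium and mesothelium markers lay above the limit and all 10 oocyte markers below it.

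Amhr2, the receptor for anti-Müllerian hormone, was 1 of the genes fixed beforehand as central to the series. Its 3 probe sets had intensities of 788 to 3496, all above background. The brightest exceeded the limit by 6.23 on the log2 scale, with an SD of 1.15 between the probe sets.

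Targets of the DNA damage checkpoint were expressed as a group in these wild-type cells. Of 18 measured targets 17 were above background, and 0.14% of random lists had as many. The call was the same under all 9 alternatives. Cdkn1a, an inhibitor of cyclin-dependent kinases, had intensities of 1107 and 1980. Mdm2, a ubiquitin ligase, had 2 of 3 probe sets above the limit, the brightest at 567, and 10 on the third. The 2 have identifiers that mark several transcripts of the same gene. Bbc3, a pro-apoptotic protein, had 225. Regulators of the checkpoint did not stand apart, with 9 of 12 above background, a count that 64.9% of random lists matched or exceeded. Mdm4, a partner of Mdm2, had 2 of 4 probe sets above the limit, the brightest at 478. Trp63 and Trp73, transcription factors of epithelial and neural development, had at most 25 and 39.

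Signalling genes were mostly above background. The Braf list holds kinases of a signalling cascade with its upstream regulators, feedback inhibitors and transcription factors. All 14 measured members of the Braf list passed the limit, as did 14 of 15 of the PI3K and AKT list. The first count was matched by 1.92% of random lists and the second by 14.8%, which stood apart under 1 of 9 alternatives. Braf had 5 of 9 probe sets above the limit, the brightest at 718, Dusp6, a phosphatase of the same cascade, had 1643, and Nras had 3 probe sets between 332 and 849. Pik3ca, the catalytic subunit of PI3-kinase, had 5 of 6 probe sets above the limit, the brightest at 769. Akt1 had 4 probe sets between 48 and 1783, and Mtor had 2 of 3 above the limit, the brightest at 489. The call for the Braf list ended under 5 of 9 alternatives.

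Genes of proliferation, survival and DNA repair were above background in larger numbers than in random lists. Of 14 measured proliferation genes 13 passed the limit, as did all 15 measured apoptosis and survival genes and all 14 measured DNA repair genes. Random lists had as many in 2.01%, 1.78% and 0.08% of draws. Mki67, a marker of cycling cells, had 574. Top2a, a topoisomerase of dividing cells, had 2 of 3 probe sets above the limit, the brightest at 569, and Cdk1, the mitotic kinase, had 713. Mcl1, an anti-apoptotic protein, had 6 probe sets between 748 and 3664. Bcl2 and Bcl2l1, related anti-apoptotic proteins, had 251 and 721 on their brightest, with 3 of 5 and 2 of 4 probe sets above the limit. Brca1, Brca2 and Palb2, proteins of homologous recombination, had 58, 110 and 76 on their brightest, and Brca1 had only 1 of 4 probe sets above the limit. The calls ended under 4 of 9 alternatives for proliferation, 3 for survival and 2 for repair.

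Among nuclear hormone receptors 9 of 11 measured members were above background, which 35.2% of random lists matched or exceeded. Esr1, estrogen receptor alpha, had 2789 on the brightest of 3 probe sets and 19 on the lowest. Pgr, the progesterone receptor, had 1 of 3 probe sets above the limit, at 228, and Esr2, estrogen receptor beta, had 17.

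Immediate early and stress genes were above background in 15 of 16 cases, as many as in 0.1% of random lists. The call was the same under all 9 alternatives. Egr1 and Fos, transcription factors induced within minutes of a stimulus, had 4954 and 1223, and Atf3, a stress-induced factor, had 184.

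Most matrix, WNT and TGF-beta genes were above background. Members above the limit numbered 11 of 12 for basement membrane and integrins, 11 of 12 for WNT and 13 of 14 for TGF-beta and BMP. These counts did not stand apart, since 12.1%, 10.5% and 7.78% of random lists had as many, but they did under 1, 2 and 3 of 9 alternatives. The list medians of 11.17, 10.15 and 10.68 on the log2 scale lay above 99.99%, 99.6% and 100% of those of random lists. Median and count did not always go together. Among lists called as having more members, the DNA repair median lay above 82.7% of random medians and that of apoptosis and survival above 91.4%. The macrophage, Braf and proliferation medians lay above 92.4%, 93.6% and 94.7%. The remaining lists called as more lay above at least 99.91%. Col4a1, a basement membrane collagen, had 7749 and 18113. Lamb1, a laminin chain, had 3 of 4 probe sets above the limit, the brightest at 3817, and Itgb1, an integrin subunit, had 3 of 6, the brightest at 4299. Ctnnb1, beta-catenin, had 3 probe sets between 203 and 8726, Wnt4, a ligand of gonad development, had 1136 and 2170, and Axin2, a feedback target of the pathway, had 637 on 1 of 2 probe sets. Smad4, the shared mediator of TGF-beta signals, had 3 probe sets between 909 and 2719, Tgfbr2, a receptor, had 2 of 3 above the limit, the brightest at 2246, and Tgfb1 had 204 on 1 of 2 probe sets and 22 on the other.

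Innate defence genes were above background in 10 of 11 measured cases, which 4.15% of random lists matched, and the count stood apart under 2 of 9 alternatives. B2m and H2-K1, parts of the class I antigen presentation complex, had 7906 and 4957 on their brightest probe sets, and Cfb, a complement factor, had 54, near the limit.

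All 10 measured ribosomal protein genes and all 13 mitochondrial respiration genes were above background, and random lists had as many in 0.7% and 0.2% of draws. Rpl4 and Rplp0 had 15717 and 19868, Rps3 had 2 of 3 probe sets above the limit, the brightest at 13555, and Cox4i1, Atp5a1 and Uqcrc1 had 10008, 5428 and 1957 on theirs. Of 11 measured genes restricted to other organs 3 were above the limit, and 2.06% of random lists had as few. The ribosomal call ended under 4 of 9 alternatives and the other-organ call under 2, while the mitochondrial call was kept. Among these alternatives was the other-organ list itself as background, where the count of that list is largely fixed by construction. Alb had 18, while Ins2 had 100 and Prm1 had 1 of 3 probe sets above the limit, at 57.

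**Figure D3:**
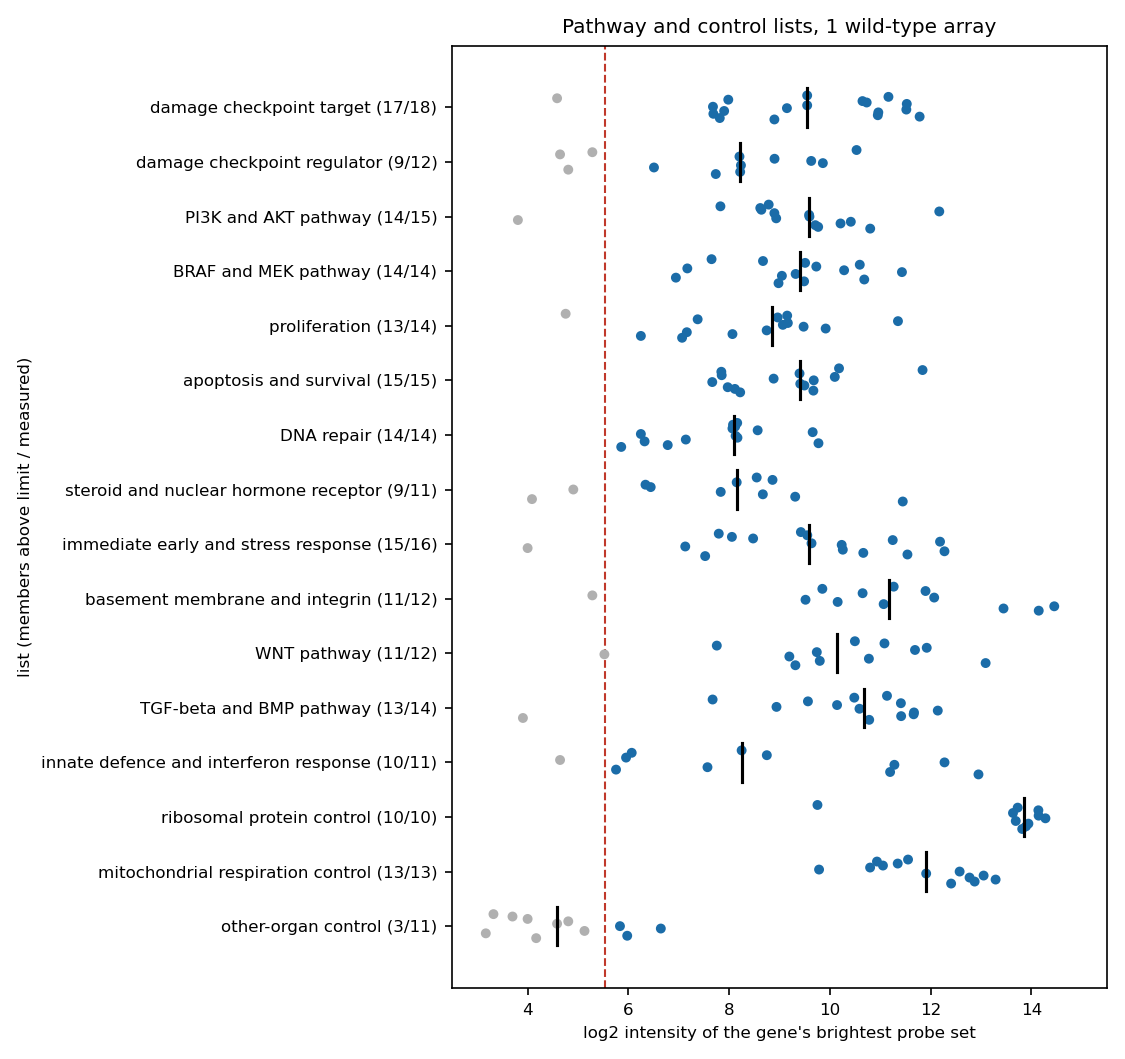
Log2 intensity of the brightest probe set (x axis) of each measured member of 13 pathway lists and 3 control lists (y axis) on the 1 wild-type array. Points are genes, blue above and grey at or below the background limit of 5.54 (dashed line), with the list median as a black bar. Of 18 checkpoint targets 17 lay above the limit, against 3 of 11 genes restricted to other organs.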

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

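All tests of explanations in this part were chosen after the values were seen. A total of 1613 of the 9160 probe sets with no gene symbol in the annotation used, or 17.6%, exceeded the background limit, and they entered no gene count. Of the 932 probe sets with several symbols 553, or 59.3%, exceeded it.

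Fibroblast and smooth muscle genes were above background in 9 of 10 cases each. Neither count stood apart from random lists, of which 7.76% and 11.1% had as many, and their difference from the endothelial list was not tested. The fibroblast and smooth muscle medians lay above 99.96% and 99.95% of those of random lists, and the endothelial median above 2.37%. Vessel fragments carried into the preparation would bring endothelial transcripts, and of the 10 endothelial markers fixed beforehand 3 passed the limit. This count was low but within that of random lists, of which 4.33% had as few, and stayed so under all 9 alternatives, so vessel fragments were not excluded. A first form of this test, on endothelial markers selected after the values were seen, left out every member that passed, and it is not used. Stromal or mural cells without vessels may account for the 18 of 20 fibroblast and smooth muscle members above background, as may transcription of these genes by the surface cells themselves. These 3 explanations cannot be told apart, because 1 mixed library does not assign a transcript to a cell.

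Macrophage genes stood above background. Blood cells carried into the preparation would bring neutrophil transcripts, and of the 8 measured neutrophil markers fixed beforehand 1 passed the limit. This was within the count of random lists, of which 5.05% had as few, while under 3 of 9 alternatives the list had fewer than random lists. A count within that of random lists cannot decide for or against blood cells. The test took this form only after 2 others. The first used the erythroid list, with 0 of 4 above the limit, and was dropped when shared probe sets of the beta-globin and alpha-globin genes were found at 148 and 85. The second used S100a8 and S100a9, at 13 and 12, which were selected after their values were seen. Blood cells cannot be told apart from macrophages of the tissue here, because 1 mixed library was measured. Macrophages in the preparation stay open and untested: the 10 of 11 members of the fixed list above background are the pattern itself. The count stood apart under 6 of 9 alternatives.

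Some granulosa and steroidogenic genes stood above background. Preantral follicles with their oocytes in the preparation would bring oocyte transcripts, of which 0 of 10 passed the limit. The outcome that would go against such follicles was set at 0 only after this count was seen. With the limit at the 90th percentile of background, or with olfactory and vomeronasal receptors as background, 3 passed. The count therefore does not decide on preantral follicles. Larger follicles, in which an oocyte is a small part, stay open too. Granulosa cells in the preparation may account for the 6 of 9 granulosa markers above background, Inha among them. No source was weighed for the 5 of 7 theca and luteal markers above background, Star among them. Neither count stood apart from random lists. Transcription of these genes in the surface cells stays open too, because 1 mixed library does not assign a transcript to a cell. In each of the 3 patterns no biological group of the design was available as an alternative, since 1 sample was analysed.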

How the results depend on the processing

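The number of genes above background was 11432 and stayed within 1.5 times of that, from 9828 to 13321, except with the lowest probe set of each gene, which gave 7228, since all of a gene's probe sets then had to pass. The 9828 came without the marked probe sets, where 16591 genes were still measured, and made up 59.2% of them. The number of lists with more members above background than random lists was 10. It was 6 with the limit at the 90th percentile and 5 with olfactory and vomeronasal receptors as background, and 8 to 11 otherwise. The number with fewer was 3. It was 0 with the 90th percentile, 1 with the receptor background and 5 with the other-organ list as background, and 2 to 4 otherwise. The 5 include the other-organ list itself, whose count is then largely fixed by construction. Of all genes 73.2% passed with the 90th percentile and 70.5% with the receptor background, against 62.8% with the main limit. With the 90th percentile the macrophage, Braf, apoptosis and ribosomal lists lost their call with unchanged counts of 10, 14, 15 and 10. Their calls ended because random lists then had more members above the limit, not because members fell to background. The oocyte, erythroid and other-organ lists lost theirs as their own counts rose to 3, 1 and 5. Of the 13 lists with a call, 4 kept it under all 9 alternatives: surface epithelium and mesothelium, damage checkpoint targets, immediate early genes and mitochondrial respiration. Of the 17 lists without a call, 8 gained one under at least 1 alternative. The median of the surface epithelium list ranged from 11.72 to 12.16. Amhr2 exceeded the limit by 6.23 on the log2 scale, by 4.08 with its lowest probe set and by 4.12 without probe sets of marked identifiers, and by 5.37 to 7.10 otherwise. The median SD between probe sets of a gene was 1.39, 1.47 without the marked probe sets and 1.80 over genes above background. Of 90 other named genes, 23 fell to background with the lowest probe set, 7 with the 99th percentile (Amh, Adgre1, Retn, Brca1, Palb2, Cfb and Prm1), 5 with the mean of a gene's probe sets (Cyp11a1, Pax8, Brca1, Pgr and Prm1) and 6 with the other-organ list as background. Of 72 still measured without the marked probe sets, Mdm2 fell, having lost 2 sets for transcripts of the same gene, and Cd3e passed. With the 90th percentile and with the receptor background 7 passed (Fshr, Cd3e, Cd3d, Gdf9, Slc4a1, Ovgp1 and Trp73), and with Y-linked genes as background Cd3e and Gdf9 did. Genes whose brightest probe set lies near the limit are thus undecided. A gene that fell only with its lowest probe set has another above the limit. No replicate could be left out, and no paired analysis was possible because 1 sample was analysed.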

Other observations

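A total of 14 gene families were taken by symbol after the values were seen. Of 44 measured keratins 13 were above background, and 0.17% of random lists had as few. Of the keratins of simple epithelia, Krt7 had 8204, Krt8 4573, Krt19 4897, Krt18 3377 and Krt20 26, below the limit. Of those of stratified epithelia, Krt10 had 177, Krt14 56, Krt5 52 and Krt1 20. Of 20 measured claudins 5 were above background, and 0.24% of random lists had as few. Cldn3 had 3923, Cldn15 1869, Cldn12 1474, Cldn10 170 and Cldn22 68. Of 20 aldehyde dehydrogenases 17 were above background, as many as in 1.17% of random lists, with Aldh1a1 at 14238 and Aldh1a2, an enzyme of retinoic acid synthesis, at 5274. Of 7 IGF binding protein genes 6 were above background, from 1852 for Igfbp4 to 12305 for Igfbp2, and Igfbp1 had 13. As a count this did not stand apart, since 23.2% of random lists had as many.

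Of 22 FGF ligands 8 were above background and of 27 interleukins 7 were, and 0.55% and 0.46% of random lists had as few. Fgf18 had 621, Il18 had 1548 and Il16 had 632. Hox genes, regulators of body position, were above background in 17 of 33 cases, with Hoxc8 at 2215, Hoxd8 at 877 and Hoxd9 at 685. Collagens did so in 27 of 42 cases, matrix metalloproteinases in 10 of 18, semaphorins in 17 of 20, chemokines in 15 of 30, BMP ligands in 5 of 10, WNT ligands in 9 of 19 and uroplakins in 3 of 6. These 8 counts lay within those of random lists. Mmp2 and Mmp14, matrix-degrading enzymes, had 10810 and 6618. Of the 14 families looked at, 4 had fewer members above background than random lists and 1 had more.

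Probe sets above an intensity of 20000, a threshold set after the values were seen, included those of Lgals1 at 32341, Col1a2 at 29972, Tpt1 at 29748, Sparc at 26924, Tsc22d1 at 25761, Tmsb4x at 25353, Fn1 at 22422 and Col3a1 at 22640, beside ribosomal proteins. Probe sets differ in affinity, so these values give no order of transcript abundance.

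Sample quality and sex were checked as values. The control probe sets of Actb had 24792 at the 3′ end and 16073 at the 5′ end, a ratio of 1.54, and those of Gapdh had 20207 and 21516, a ratio of 0.939. Xist, transcribed from the inactive X chromosome of females, had 3 probe sets from 144 to 6070. Of 13 probe sets for Y-linked genes 1 exceeded the background limit, a probe set of Sry at 77, and the 11 of the other 5 genes had at most 27.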
